A study of Homo sapiens with 4 samples.

How the data were processed

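RNA from NB4 cells, 2 samples untreated and 2 treated with WEB-2170, all at 24 hours, was labelled in a one-cycle reaction and hybridised to Affymetrix human genome GeneChip arrays, per the labels' protocols. The deposited table gives 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes the values come from GCOS, the array maker's operating software; its version, the summary algorithm and any scaling target are not given in the sources used here. The 2% trimmed means of the deposited intensity values were equal on the 4 arrays, at about 330.1, within the tolerance of 10% set for quantile normalisation, so the values were used as the authors scaled them. Such scaling sets the arrays' average signal equal, so a change in the total messenger RNA per cell is not visible in these values.

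Of 22283 probe sets 68 controls were left out. Of the other 22215, 19065 had 1 gene symbol in the platform annotation used, 1043 had several and 2107 had none there. The identifier of 19053 of the first kind was found in the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. Probe sets with several genes were tested but not named. Some genes of the fixed lists, and 1 gene of the named genes' rule, are not reported here.

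Intensities entered as log2(intensity + 16), so fold changes understate the change of dim genes. Probe sets under the 40th percentile of mean log2 value were left out, leaving 13329 probe sets and 7982 genes. A gene was represented by its tested probe set with the highest mean value; 2567 genes had more than 1 tested probe set. Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend; prior degrees of freedom 7.87), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Changes are WEB-2170 minus untreated. The number of arrays, 2 per group, limits the precision. The 28 gene lists, chosen for this cell type and compound, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested genes. Lists of other blood lineages and of fibroblast and epithelial cells were among them, and no cell type was assigned from any list. Per-array ratios of 3' to 5' controls were compared by exact permutation.

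The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 largest rises and the 12 largest falls among called genes whose arrays did not overlap between groups. It also took the 2 largest rises and 2 largest falls among the called members of each list (where no member was called, the 2 members of smallest p), and 12 genes chosen in advance, 11 of which were tested: PTAFR, MYC, HEXIM1, BCL2, BCL2L1, MCL1, CDKN1A, CDKN1B, CCND2, MPO and ITGAM. It gave 108 genes, 103 of them called. Part of these are printed, and where a printed gene's call was lost with an array left out, or under another setting that ended it, that is given beside it. HNRNPDL was named after its values were seen.

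The fit and camera were tested on 20 simulated sets of 2 against 2 arrays, with 200 changed probe sets in each. The 13329 probe sets tested here kept their measured means. Their spread was smoothed over the mean and their noise was independent, so recovery may be flattered and correlated genes were not tried. Of changes of 0.5, 1 and 2 log2, 11.2%, 72.0% and 99.5% were recovered, and 4.59% of calls were false. Of lists of 25 genes, 20 of 20 that were shifted by 0.6 log2 had an unadjusted camera p under 0.05, and 0 of 20 unshifted ones. The adjustment over lists was not tried there. The shifted genes came on top of the 200 changed probe sets.

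The alternatives were pseudocounts of 1 and 64, quantile normalisation, centring each array on its median, no filter, a filter at the 60th percentile, no intensity trend, a robust prior, array weights, the replicate number as a block, leaving out each array, the mean of a gene's probe sets, other thresholds, camera with an estimated correlation and fry. With 1 array left out, the lone array of a group is assumed to vary like the other group.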

Results

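Gene expression was measured in NB4 cells, a human acute promyelocytic leukaemia line that carries the PML-RARA fusion, after 24 hours with or without WEB-2170. WEB-2170 is an antagonist of the platelet-activating factor receptor, and the series was designed to look into how it acts on acute myeloid leukaemia cells. Total RNA was hybridised to Affymetrix human genome GeneChip arrays, with 2 untreated arrays and 2 WEB-2170 arrays. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. They give neither the dose of WEB-2170 nor a vehicle. Any effect of a solvent can therefore not be told apart from that of WEB-2170. All arrays had a 2% trimmed mean intensity of about 330.1. The log2 values of the 13329 probe sets tested correlated at 0.970 between the untreated arrays and at 0.971 between the treated arrays, against 0.922 to 0.938 for pairs of an untreated and a treated array. The log2 ratio of the 3' to the 5' control probe set was 0.00 ± 0.01 untreated and 0.02 ± 0.02 treated for ACTB (SD, n = 2 arrays each; exact two-sided permutation p = 0.67). For GAPDH it was -0.26 ± 0.00 untreated and -0.22 ± 0.06 treated (SD, n = 2; exact permutation p = 0.67), and 0.33 is the smallest p that 2 against 2 arrays can give. For the ISGF3A control the ratio was 2.63 ± 0.09 untreated and 2.33 ± 0.18 treated (SD, n = 2; exact permutation p = 0.33), with the arrays of the groups apart. For 28S ribosomal RNA, 5 of 6 control probe sets were higher on both treated arrays than on both untreated arrays, 3 of them by at least 1.5 times.

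After WEB-2170, the lists of primary granule and promyelocyte genes and of MYC and ribosome biogenesis genes fell, by camera with a preset correlation. Those of lysosome and autophagy genes, p53 targets and histone genes with HEXIM1 rose by the same test. With an estimated correlation these list calls were lost (adjusted p = 0.34 to adjusted p = 0.49). With 2 arrays per group that correlation is poorly estimated, so the loss cannot decide whether the lists changed. Of 7982 genes tested, 1288 (16.1%) were called at an adjusted p under 0.05 by limma, 697 higher and 591 lower. Of these, 419 were higher and 331 lower by at least 2-fold, and 43 were higher and 44 lower by at least 4-fold. In 4537 of the 7982 tested genes (56.8%) both treated arrays lay on the same side of both untreated arrays, an arrangement that chance gives in 33.3% of genes, and the called genes were among them. Each array centred on its median gave 542 genes higher and 712 lower in place of 697 and 591. Without an intensity trend in the prior 669 genes were called, and the number fell to 756 without untreated replicate 1 and to 770 without untreated replicate 2. One gene, HNRNPDL, had probe sets called in opposite directions, at -1.04 and 0.69 log2.

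LTB, which encodes lymphotoxin beta, rose from an intensity of 259 ± 41.8 to 2784 ± 409 (SD, n = 2; log2 change 3.35, SE 0.21, adjusted p = 6.07e-05). ALOX5AP, the protein that presents arachidonic acid to 5-lipoxygenase in leukotriene synthesis, rose from 117 ± 17.6 to 1173 ± 140 (SD, n = 2; adjusted p = 7.89e-05). GCHFR, the feedback regulator of GTP cyclohydrolase, rose by 3.24 log2 (SE 0.29). The semaphorin receptor PLXNC1 rose by 3.10 log2 (SE 0.33), and UNC119, which carries acylated proteins to membranes, by 3.03 (SE 0.35). SERPINI1, which encodes neuroserpin, rose from 21.8 ± 3.58 to 270 ± 10.6 (SD, n = 2; adjusted p = 0.000525). The chaperone gene CLU rose by 2.90 log2 (SE 0.31), and the DNA sensor IFI16 by 2.79 (SE 0.19). DPYSL2, PRF1, which encodes perforin, and the glycogen phosphorylase PYGB rose by 2.75, 2.68 and 2.67 log2. A pseudocount of 64 moved the fold of 19 of the 103 named genes called by over 1.5 times, and gave PLXNC1 2.33, UNC119 1.97, SERPINI1 1.96 and PYGB 1.93 log2.

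LRFN4, a synaptic adhesion-like protein, fell from 695 ± 94.2 to 13.2 ± 1.16 (SD, n = 2; log2 change -4.60, SE 0.26, adjusted p = 5.69e-05). Its treated values lay below the 25th percentile of their arrays (14.9 and 21.2), so the size of its change moves with the pseudocount, to -3.29 log2 with a pseudocount of 64. Probe sets for TRDV3, a variable segment of the T-cell receptor delta locus, and COL4A2, a type IV collagen chain, changed by -4.08 and -3.59 log2. HDC, the enzyme that makes histamine, changed by -3.58 log2 (SE 0.54), from 758 ± 267 to 64.2 ± 70.3 (SD, n = 2). DHRS9, a retinol dehydrogenase, changed by -3.57 (SE 0.27), and GJA1, which encodes connexin 43, by -3.22 (SE 0.41). The AP-1 subunit gene FOSL1 changed by -3.19 log2 (SE 0.49) and the potassium channel gene KCNH2 by -3.02 (SE 0.29). With a pseudocount of 64 the changes of HDC, DHRS9 and FOSL1 were -2.76, -2.82 and -2.13 log2. The probe set that represented QTGAL was at -3.24 log2 (SE 0.38), but its treated intensity of 5.07 ± 0.25 (SD, n = 2) lay near the 10th percentile of the arrays (4.24 and 6.73), so the pseudocount sets that size (-1.84 with a pseudocount of 64). Another probe set of QTGAL was at -0.84 (SE 0.43, adjusted p = 0.24). With a pseudocount of 1 the first was removed by the filter and the other took its place, at -1.12 log2 (adjusted p = 0.25).

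**Figure D1:**
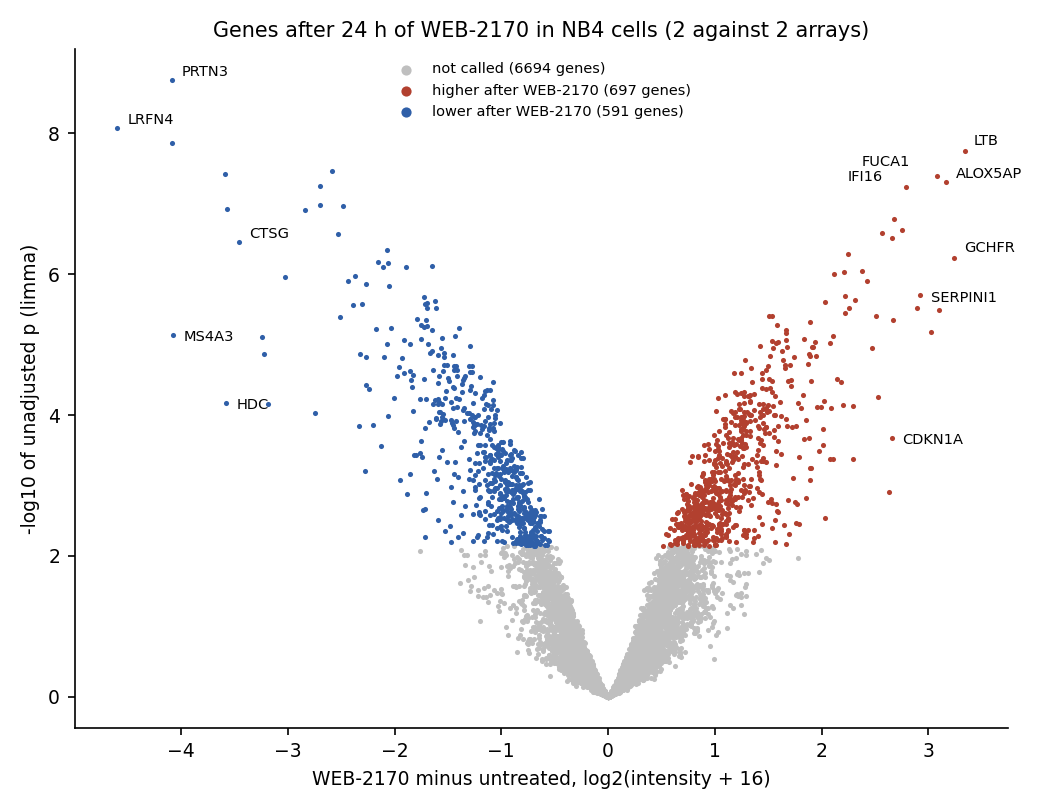
Each point is 1 of 7982 genes; the x axis is the log2 difference between WEB-2170 and untreated arrays (log2 of intensity plus 16) and the y axis -log10 of the unadjusted limma p. The 697 genes called higher are red and the 591 called lower blue, with LTB at 3.35 and LRFN4 at -4.60 as the outermost points on the x axis.

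Azurophil granule and promyelocyte genes fell together. Azurophil granules are the primary granules that mark the promyelocyte stage. The list also holds genes of other kinds, such as the transcription factor genes MYB and CEBPE. Of 18 tested members 12 were lower, 1 was higher and 5 were not called (13 lower and 1 higher adjusted over the list alone), with a median log2 change of -1.24. The list was called by camera (adjusted p = 3.5e-12 with the preset correlation; adjusted p = 0.34 with an estimated correlation). PRTN3, the serine protease proteinase 3, went from 4932 ± 289 to 277 ± 55.9 (SD, n = 2; log2 change -4.09, SE 0.20). MS4A3, a membrane protein of granulocyte progenitors, went from 2676 ± 965 to 169 ± 145 (SD, n = 2; log2 change -4.08, SE 0.48). CTSG, which encodes cathepsin G, changed by -3.46 log2 (SE 0.29; -2.49 with a pseudocount of 64), and MPO, which encodes myeloperoxidase, from 10475 ± 1735 to 3931 ± 6.85 (SD, n = 2; log2 change -1.40, SE 0.16). SERPINB1, an inhibitor of these proteases, was the member called higher, at 1.33 log2 (SE 0.21).

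The list of later granulocytic genes was not called (adjusted p = 0.86; median 0.20). Of 25 tested members 4 were higher, 3 lower and 18 not called (6 higher and 3 lower adjusted over the list alone). ITGAM, the CD11b chain of the complement receptor, was higher, from 147 ± 15.4 to 357 ± 46.5 (SD, n = 2; log2 change 1.19, SE 0.23), but its call was lost with the mean of its probe sets (0.50 log2, adjusted p = 0.23). S100A8, a calcium-binding protein of neutrophils, was higher by 1.73 log2 (SE 0.36; 1.13 with a pseudocount of 64), though not called when no probe sets were filtered (adjusted p = 0.052), and CEBPD, a transcription factor of myeloid maturation, changed by -2.01 (SE 0.30). Retinoic acid receptor targets were not called (adjusted p = 0.60), with 1 of 16 higher and 3 lower (2 and 3 adjusted over the list alone), among them ID2 at 2.10 log2 (SE 0.25) and CEBPE at -1.37 (SE 0.25). Monocyte and macrophage markers were not called either (adjusted p = 0.55; median 0.11), with 5 of 14 higher and 1 lower, the same numbers adjusted over the list alone. The largest rises were those of LGALS3 at 1.86 log2 (SE 0.43) and CD86 at 1.57 (SE 0.37; 0.93 with a pseudocount of 64). Without a filter neither was called (adjusted p = 0.052 and 0.063). LGALS3 also lost its call without an intensity trend (adjusted p = 0.088) or untreated replicate 1 (1.10 log2). CD86 lost its call without untreated replicate 2 (1.45 log2) or WEB-2170 replicate 1 (1.46 log2). CSF1R, the receptor of macrophage colony-stimulating factor, was the lower one at -1.86 log2 (SE 0.38; -1.11 with a pseudocount of 64), and was not called without untreated replicate 1 (-1.57, adjusted p = 0.12). Erythroid and megakaryocytic genes (1 of 18 higher, 3 lower; median -0.27, adjusted p = 0.061), lymphoid markers (1 of 14 higher, 1 lower; median 0.11, adjusted p = 0.85) and fibroblast and epithelial markers (1 of 10 higher; median 0.26, adjusted p = 0.60) were not called. Adjusted over the list alone, the erythroid and lymphoid numbers were the same, and 1 fibroblast or epithelial marker was higher and 1 lower. The erythroid list was called lower without untreated replicate 1 (adjusted p = 0.046). The erythroid transcription factor gene NFE2 changed by -1.49 log2 (SE 0.21).

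MYC and ribosome biogenesis genes fell as a group: 18 of 27 tested members were lower and 9 were not called (22 lower adjusted over the list alone; median -0.90). The camera adjusted p was 5.89e-15 with the preset correlation, and adjusted p = 0.34 with an estimated correlation. The proto-oncogene MYC fell from 5363 ± 918 to 1744 ± 791 (SD, n = 2; log2 change -1.68, SE 0.28, adjusted p = 0.00386). RRP12 and MRTO4, factors of ribosomal subunit assembly, changed by -2.43 (SE 0.23) and -2.11 (SE 0.19) log2, and the mean of its probe sets put RRP12 at -1.57. For cytosolic ribosomal proteins, 0 of 30 tested members were called by limma, also adjusted over the list alone, and 2 had an unadjusted p under 0.05. That list was not called (median 0.05, adjusted p = 0.86). Its smallest p values were those of RPL12 at 0.36 log2 (SE 0.14, adjusted p = 0.13) and RPLP1 at 0.34 (SE 0.13, adjusted p = 0.13). RPL12 rested on a probe set ending in _x_at. Without such probe sets, a setting chosen after the data were seen, 24 members were tested and 0 called.

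Histone genes and HEXIM1, which encodes an inhibitor of the elongation factor P-TEFb, rose: 4 of 7 tested members were higher and 3 not called (6 higher adjusted over the list alone; median 1.09 log2). Camera gave an adjusted p of 0.00015 for this list (adjusted p = 0.34 with an estimated correlation). HEXIM1 went from 229 ± 42.8 to 755 ± 82.4 (SD, n = 2; log2 change 1.66, SE 0.22, adjusted p = 0.00148). The histone genes H2AC6 and H2BC5 rose by 2.20 (SE 0.34) and 1.96 (SE 0.30) log2. H2AC6 was among the genes whose fold moved by over 1.5 times with a pseudocount of 64. H2BC5 rested on a probe set ending in _x_at. Without such probe sets, a setting chosen after the data were seen, 3 of 6 tested members were higher.

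p53 target genes rose, with 10 of 20 tested members higher, 2 lower and 8 not called (11 higher and 2 lower adjusted over the list alone; median 0.89). The camera adjusted p was 0.00039 (adjusted p = 0.34 with an estimated correlation). FUCA1, a lysosomal fucosidase, rose from 232 ± 10.9 to 2104 ± 402 (SD, n = 2; adjusted p = 7.85e-05), and the cyclin gene CCNG2 rose by 2.66 log2 (SE 0.22). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 38.8 ± 37.0 to 299 ± 117 (SD, n = 2; log2 change 2.66, SE 0.47, adjusted p = 0.00534; 1.83 with a pseudocount of 64). The exonuclease gene AEN went the other way, at -1.61 log2 (SE 0.26). Cyclin-dependent kinase inhibitors and G1 regulators were not called as a list (adjusted p = 0.31), with 7 of 19 higher and 2 lower (9 and 4 adjusted over the list alone; median 0.33). In that list CCND2, which encodes cyclin D2, fell from 3125 ± 554 to 942 ± 380 (SD, n = 2; log2 change -1.76, SE 0.26), and CDK4, its kinase partner, by -1.08 log2 (SE 0.16). CDKN1B, the inhibitor p27, was higher by 0.90 log2 (SE 0.24, adjusted p = 0.033), but was not called without untreated replicate 1 (adjusted p = 0.14), untreated replicate 2 (adjusted p = 0.079) or WEB-2170 replicate 2 (adjusted p = 0.20), nor with either rescaling (adjusted p = 0.056 with quantile normalisation and 0.052 with median centring). Its call was also lost without a filter (adjusted p = 0.061) and without an intensity trend (adjusted p = 0.097).

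Genes of DNA replication and of mitosis were not called as lists. For G1/S transition and DNA replication the median log2 change was 0.02 (adjusted p = 0.97), with 2 of 35 higher and the rest not called (1 higher adjusted over the list alone). The thymidine kinase gene TK1 was higher by 1.07 log2 (SE 0.21), though not called without untreated replicate 1 (adjusted p = 0.062). For G2/M phase and mitosis the median was 0.20 (adjusted p = 0.14), with 5 of 40 higher and the rest not called, the same number adjusted over the list alone. HMMR, a hyaluronan receptor bound to the spindle, rose by 1.11 log2 (SE 0.19).

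Apoptosis effectors and the BCL2 family went both ways and were not called as a list (adjusted p = 0.97; median -0.02), with 6 of 37 higher and 3 lower, the same numbers adjusted over the list alone. The anti-apoptotic gene BCL2 was lower, from 680 ± 133.1 to 279 ± 72.4 (SD, n = 2; log2 change -1.25, SE 0.24, adjusted p = 0.00876), but was not called without untreated replicate 2 (-1.05, adjusted p = 0.059) or with the mean of its probe sets (-0.75, adjusted p = 0.17). BNIP3L, a mitophagy receptor, rose by 2.11 log2 (SE 0.20). BCL2L1 and MCL1, anti-apoptotic members of the same family, were not called: BCL2L1 was at -0.71 log2 (SE 0.27, adjusted p = 0.11) and MCL1 at 0.41 (SE 0.22, adjusted p = 0.27). Without WEB-2170 replicate 1 BCL2L1 was called lower (-0.98 log2, adjusted p = 0.040), and without WEB-2170 replicate 2 it was at -0.45. MCL1 was at 0.15 without untreated replicate 2 and at 0.66 without untreated replicate 1.

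Lysosome and autophagy genes rose, with 16 of 36 tested members higher, 2 lower and 18 not called (20 higher and 3 lower adjusted over the list alone; median 0.61). The camera adjusted p was 3.45e-05 (adjusted p = 0.49 with an estimated correlation). PSAP, the precursor of the saposins, rose from 1790 ± 343 to 5328 ± 771 (SD, n = 2; log2 change 1.57, SE 0.19), and WIPI1, which acts in autophagosome formation, rose by 2.14 log2 (SE 0.30; 1.44 with a pseudocount of 64). The 2 members called lower, CLN3 at -0.83 log2 and CTSH at -0.63, were not called without untreated replicate 1 (adjusted p = 0.080 and 0.068), untreated replicate 2 (0.094 and 0.26) or WEB-2170 replicate 1 (0.055 and 0.12), nor without an intensity trend (0.063 and 0.14). CLN3 was also not called without probe sets ending in _x_at, a setting chosen after the data were seen, in which another probe set represented it (-0.49 log2, adjusted p = 0.28), and CTSH with quantile normalisation (adjusted p = 0.085) or without a filter (adjusted p = 0.071).

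Heat shock proteins fell, with 3 of 14 lower and 11 not called (7 lower adjusted over the list alone; median -0.48). The camera adjusted p was 0.00244 (adjusted p = 0.43 with an estimated correlation). The small heat shock protein gene HSPB1 changed by -1.76 log2 (SE 0.21) and HSPA9, the mitochondrial HSP70, by -1.20 (SE 0.16). The list of ATF4 targets and the unfolded protein response fell as well, with 11 of 37 lower, 3 higher and 23 not called (14 lower and 4 higher adjusted over the list alone; median -0.24). Its camera adjusted p was 0.00564 (adjusted p = 0.43 with an estimated correlation). SLC7A5, a transporter of large neutral amino acids, went from 3473 ± 28.4 to 779 ± 168 (SD, n = 2; log2 change -2.15, SE 0.19). The chaperone gene HSP90B1 changed by -1.70 (SE 0.18), on a probe set ending in _x_at. ASNS, which encodes asparagine synthetase, and DDIT4, an inhibitor of mTORC1, rose by 1.56 (SE 0.23) and 1.48 (SE 0.23) log2.

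Interferon-stimulated genes rose, with 8 of 31 higher, 2 lower and 21 not called (12 higher and 3 lower adjusted over the list alone; median 0.44). The camera adjusted p was 0.0317 (adjusted p = 0.43 with an estimated correlation), and the call was lost without untreated replicate 2 (adjusted p = 0.076), without WEB-2170 replicate 1 (adjusted p = 0.054), without a filter (adjusted p = 0.051) and with a filter at the 60th percentile (adjusted p = 0.11). IFI16 rose by 2.79 log2, and IFITM1, an interferon-induced membrane protein, changed by -1.26 (SE 0.19). Immediate early genes rose, with 8 of 25 higher, 3 lower and 14 not called (10 higher and 3 lower adjusted over the list alone; median 0.56). The camera adjusted p was 0.0393 (adjusted p = 0.56 with an estimated correlation), and the call was lost without untreated replicate 2 (adjusted p = 0.16), without WEB-2170 replicate 1 (adjusted p = 0.42) and with a filter at the 60th percentile (adjusted p = 0.11). The phosphatase gene DUSP6 rose by 1.89 log2 (SE 0.21) and KLF6, a zinc finger factor, by 1.88 (SE 0.33; 1.28 with a pseudocount of 64), while FOSL1 and MYC fell.

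The receptor of platelet-activating factor, PTAFR, was at 217 ± 13.2 untreated and 145 ± 41.8 treated (SD, n = 2; log2 change -0.55, SE 0.26, adjusted p = 0.20) and was not called. Without WEB-2170 replicate 1 it was at -0.28. Its probe set ends in _x_at, and without such probe sets, a setting chosen after the data were seen, PTAFR was not tested. Genes of platelet-activating factor metabolism were not called as a list (adjusted p = 0.85; median 0.21), with 1 of 12 higher and 3 lower, the same numbers adjusted over the list alone. PAFAH1B3, a subunit of the enzyme that inactivates this lipid, was at -1.20 log2 (SE 0.28), though not called without untreated replicate 2 (-0.86, adjusted p = 0.11) or without an intensity trend (adjusted p = 0.063). The PI3K and AKT signalling list was not called (adjusted p = 0.85; median 0.09), with 4 of 23 higher and 3 lower, the same numbers adjusted over the list alone. Its members included the pseudokinase genes TRIB2, at 2.43 log2 (SE 0.23), and TRIB1, at -1.55 (SE 0.25). NF-kB and inflammatory targets were not called (adjusted p = 0.55; median 0.17), with 5 of 22 higher and 1 lower (6 and 1 adjusted over the list alone). The adhesion molecule gene ICAM1 rose by 1.34 log2 (SE 0.21), and the chemokine gene CCL20 changed by -1.74 (SE 0.33).

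Among metabolic lists, oxidative stress and NRF2 targets had 8 of 26 members higher and the rest not called (9 higher and 3 lower adjusted over the list alone; median 0.28, adjusted p = 0.058). The list was called in 7 other settings, with adjusted p from 0.011 without WEB-2170 replicate 1 to 0.046 with a filter at the 60th percentile. The malic enzyme gene ME1 and the quinone reductase gene NQO1 rose by 1.30 (SE 0.21) and 1.25 (SE 0.17) log2. Cholesterol synthesis and SREBP targets were not called (adjusted p = 0.97; median 0.06), with 2 of 26 higher and 4 lower, the same numbers adjusted over the list alone. TM7SF2, a sterol reductase, rose by 2.51 log2 (SE 0.27), and FASN, which encodes fatty acid synthase, was at -1.44 (SE 0.30), though not called without untreated replicate 2 (adjusted p = 0.056) or without an intensity trend (adjusted p = 0.065), and at -0.92 without WEB-2170 replicate 2. Glycolysis and hypoxia targets (7 of 29 higher, 2 lower; median -0.05, adjusted p = 0.86) and oxidative phosphorylation (2 of 47 higher, 2 lower; median -0.06, adjusted p = 0.85) were not called, with the same numbers adjusted over the list alone. NDRG1, a hypoxia-responsive gene, rose from 174 ± 0.293 to 528 ± 122 (SD, n = 2; adjusted p = 0.00302). The proteasome list was not called by camera (adjusted p = 0.058; median -0.15), with 2 of 28 lower, also adjusted over the list alone, and PSMB5, a catalytic subunit, at -1.14 log2 (SE 0.16). The proteasome list was called lower without untreated replicate 2 (adjusted p = 0.042).

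**Figure D2:**
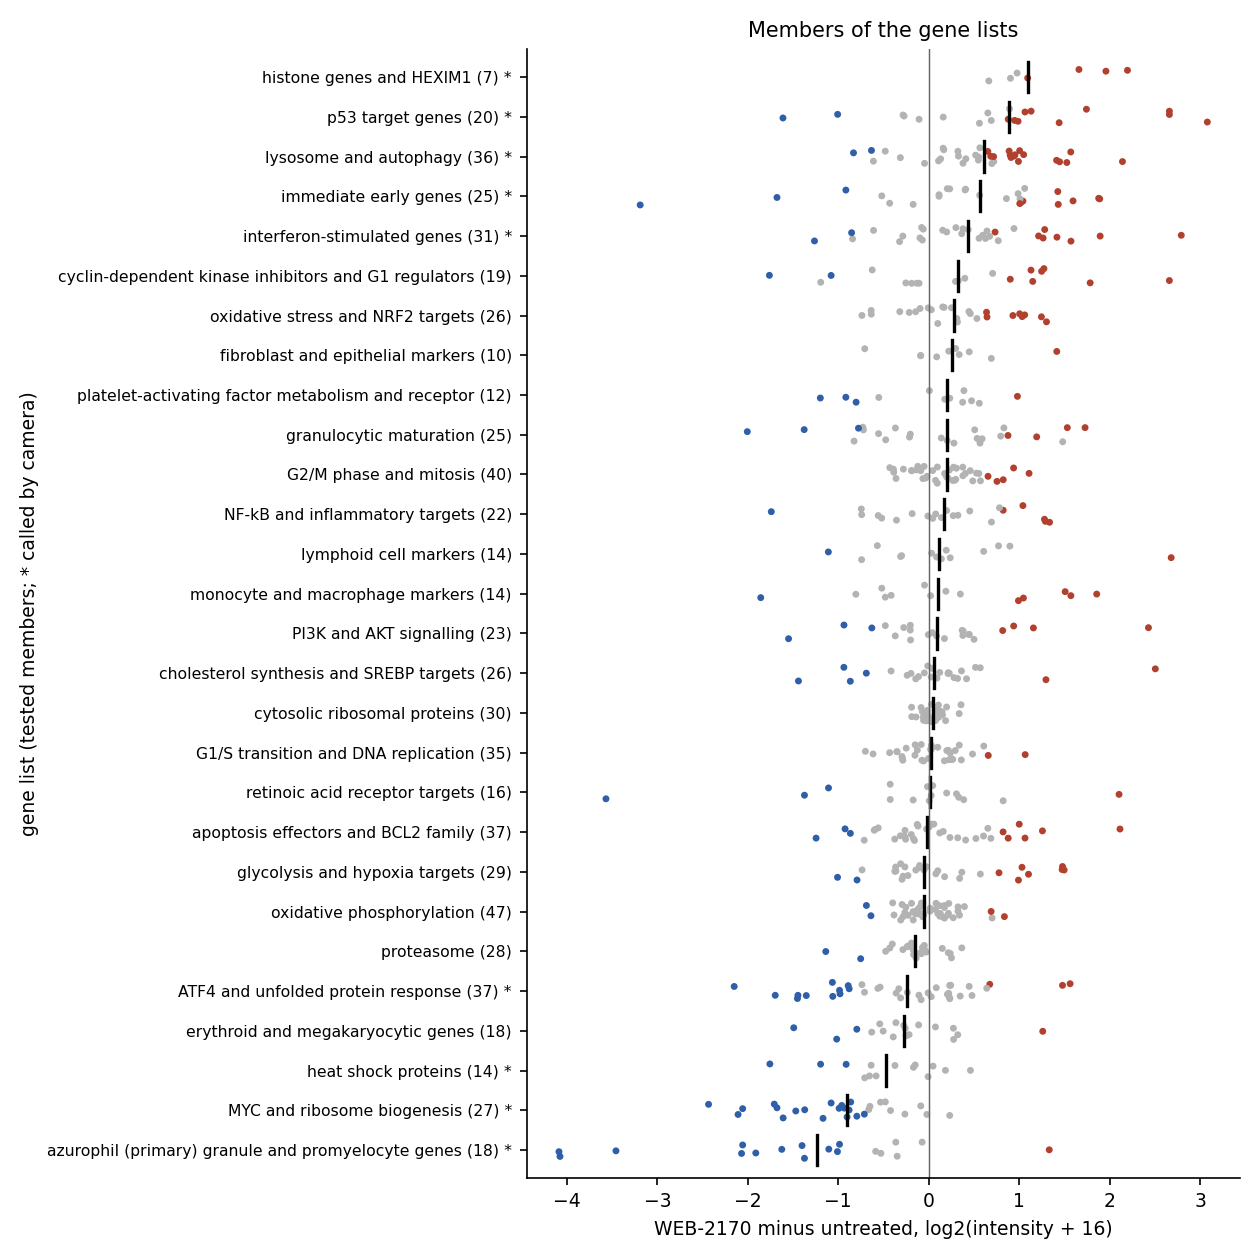
Each point is a tested member of 1 of 28 gene lists, placed by its log2 difference between WEB-2170 and untreated arrays (x axis, log2 of intensity plus 16); red members were called higher, blue lower and grey neither, a black line marks each list's median and an asterisk a list called by camera. The medians ran from -1.24 for azurophil granule and promyelocyte genes to 1.09 for histone genes and HEXIM1.

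With the preset correlation 9 of 28 lists were called, 5 higher and 4 lower. With a correlation estimated from these arrays 0 of these 9 calls held, and 4 lists had an unadjusted camera p under 0.05. The fry test called 6 lists: MYC and ribosome biogenesis, azurophil granule and promyelocyte, histone and HEXIM1, p53 target, interferon-stimulated and proteasome genes. Camera sets a list against the other genes, whose median change was 0.07 log2, and the median, the mean and the test differed in sign for retinoic acid receptor targets, platelet-activating factor metabolism, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, G1/S transition and apoptosis.

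**Figure D3:**
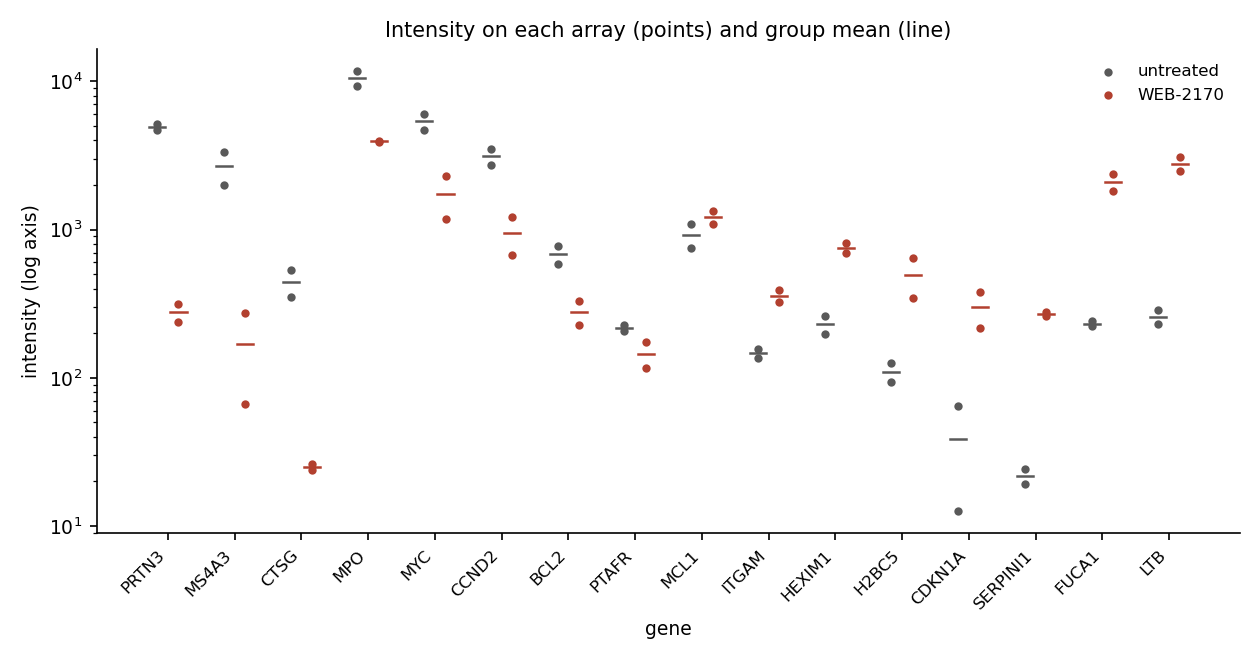
Intensity (log axis) of 16 genes on each array, with 2 points per group and a line at the group mean. PTAFR and MCL1 were not called, and the other genes shown were called, with PRTN3 at 4932 untreated and 277 treated and LTB at 259 and 2784.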

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

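Both tests of the pattern below were chosen after the result was seen. The arrays carry 23 control probe sets for human RNA, which were left out of the comparison of genes. In 3 of them both treated arrays lay at least 1.5 times above the higher untreated array, and all 3 measure 28S ribosomal RNA. The lower treated array stood at 2.87 times the higher untreated array for the middle 28S probe set, with intensities of 574 and 346 untreated and 3739 and 1646 treated. That ratio was 1.65 for the 5' 28S probe set (825 and 446 untreated, 2244 and 1359 treated) and 1.81 for an older 28S probe set (31.0 and 47.0 untreated, 103 and 85.3 treated). The other 3 28S probe sets stayed within that bound, with mean log2 differences of 0.28, 0.28 and 0.83.

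Degraded messenger RNA would raise the ratio of 3' to 5' controls. The mean log2 ratio over ACTB, GAPDH and ISGF3A rose by at most 0.00037 in any pair of a treated and an untreated array, which argues against it. More ribosomal RNA carried into labelling would raise 18S probe sets as much. Over all 6 28S and all 6 18S probe sets, the mean rise of 28S exceeded that of 18S by 1.35 log2 between the arrays numbered 1 and by 0.17 between those numbered 2. These values lie on either side of the bounds set for this test, so with 2 arrays per group a labelling difference and an effect of WEB-2170 on ribosomal RNA cannot be told apart.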

How the results depend on the processing

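The setting that leaves out probe sets ending in _x_at was chosen after the data were seen. The main counts were 1288 genes (697 higher, 591 lower) and 9 lists. Without an intensity trend 669 genes were called (366 higher, 303 lower), and with at least a 2-fold change 750 (419 higher, 331 lower); the second follows from its own construction, and the cause of the first was not tested. Leaving out 1 array gave 756 to 1244 genes, 435 to 631 higher and 316 to 613 lower, and 8 to 10 lists; fewer arrays were fitted. With the replicate block 2299 genes were called (1279 higher, 1020 lower) and 10 lists, and it added calls for the printed genes BCL2L1 (adjusted p = 0.018), RPL12 (adjusted p = 0.036) and RPLP1 (adjusted p = 0.046), which made 2 of 30 ribosomal protein genes higher. The labels give the replicates only a number, and same-numbered arrays deviated from their group means with a correlation of 0.37 over probe sets, from 2 pairs. Camera with an estimated correlation called 0 lists, and fry called 6. That correlation was estimated from only 2 arrays per group, so lost calls cannot decide whether a list changed. The cause of the loss was not tested. Lists not called in the main setting were called in others: oxidative stress and NRF2 targets in 7, proteasome in 5, erythroid genes in 3, G2/M in 2 and monocyte markers in 1. In the other settings 918 to 1773 genes and 8 to 12 lists were called. Genes called both in the main setting and in another had the same direction in each. Median centring moved the median change of all genes by -0.10 log2. Leaving out an array was an uneven check. For the genes given as single values below, adjusted p rose when an untreated array was left out. It fell when a treated array was left out, except for MXD3 without WEB-2170 replicate 2. The cause of these falls was not tested. A call kept or gained without a treated array is therefore the weaker check. Of 103 named genes called, 63 kept the call in every setting that tested them, 37 lost it with an array left out and 0 changed sign. Depth is not given by arrays: signal near background limits dim genes, whose change moves with the pseudocount.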

Other observations

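Genes beyond those fixed in advance, chosen after their values were seen, are given here as single values, with no theme tested. The RNA polymerase I subunit gene POLR1G changed by -2.06 log2 (SE 0.33, adjusted p = 0.00353), the nucleolar helicase gene DDX31 by -2.26 (SE 0.32) and the importin gene IPO4 by -2.27 (SE 0.22). TERT, the catalytic subunit of telomerase, changed by -2.33 log2 (SE 0.39, adjusted p = 0.00411), and BCAT1, a branched-chain amino acid transaminase, by -2.33 (SE 0.29). The nucleotide receptor gene P2RY2 was at -2.83 log2 (SE 0.21) and the complement receptor gene C3AR1 at -2.20 (SE 0.37). CD48, CD9 and ICAM4, which encode surface proteins, rose by 2.25 (SE 0.24), 2.21 (SE 0.21) and 2.30 (SE 0.35) log2. The kinase gene SGK1 rose by 2.18 log2 (SE 0.31), and MXD3, a MAX-binding repressor of the MYC network, by 2.08 (SE 0.40). Dim values move with the pseudocount: with 64 the changes were -1.34 for TERT, whose treated values lay below the 25th percentile of their arrays, -1.45 for DDX31, -1.46 for C3AR1, 1.27 for MXD3 and 1.71 for ICAM4, and the fold of SGK1 moved by over 1.5 times.

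HEXIM1, SERPINI1 and histone genes rose while MYC fell, a set of changes known from inhibitors of BET bromodomain proteins, and WEB-2170 shares a thieno-triazolo-diazepine core with the BET inhibitor JQ1. The tests of array scaling, of a stop of cell division and of a block of transcription were chosen after the result was seen. The genes of the BET inhibition test were set before that test was run. The pattern itself was drawn from these data, as SERPINI1 was named for the size of its rise. Of the BET test's genes, MYB and CCR2 were also members of lists tested above, so that test is not independent of them. Array scaling is argued against only as far as the rescalings reach. Median centring moved the median change of all genes by just -0.10 log2. The 6 called members kept their direction with changes of at least 0.997 log2 under both rescalings. G1/S and G2/M genes had a median of 0.096 log2, so they did not fall together. That cannot exclude a stop of cell division in which these transcripts are kept. Immediate early genes without MYC had a median of 0.71 (0.45 without WEB-2170 replicate 1 and 0.47 without untreated replicate 2). So these genes did not fall together. That list had already been seen to rise with MYC in it, so this outcome was known in advance. It cannot decide whether transcription was blocked. Of 10 genes set beforehand as responders to BET inhibitors 6 were tested and 3 called, all in that direction and 0 in the other. The called genes were MYB at -2.06 log2 (-1.43 with the mean of its probe sets), TXNIP at 0.94 and ZCCHC24 at 0.90. SAT1 at 0.18, CCR2 at -0.81 and FLT3 at 0.50, against its direction, were not called. BET inhibition is a candidate explanation, but ZCCHC24 was not called without untreated replicate 2 (0.79 log2, adjusted p = 0.096) or without an intensity trend (adjusted p = 0.059), which leaves fewer than the 3 genes set as the bound, MYB belongs to a list already seen to fall, and the platelet-activating factor receptor, other targets and an indirect effect of the fall in MYC were not tested and stay open.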
